A study of Mus musculus with 6 samples.

How the data were processed

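The series holds 6 RNA-seq libraries of CD31-positive cells from lungs of mouse pups on postnatal day 7. Of these, 3 came from animals in room air (21% oxygen) and 3 from animals in hyperoxia (75% oxygen) since postnatal day 0. Lungs were minced, digested warm with an enzyme blend, dissociated mechanically, labelled with CD31 microbeads and passed over a magnetic column. Libraries were made with the VAHTS Universal V8 kit. Bead selection can carry other cells along, and warm digestion can induce immediate early genes, so gene lists for both were included. Groups and replicate numbers came from the sample titles. The labels do not say that the replicates were separate animals, so p-values measure the spread between these samples.

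The deposited values were raw counts for 56941 Ensembl gene IDs. Per the submitters' processing notes, HISAT2 2.2.1, featureCounts, Subread 2.0.6, DESeq2 and the genome build GRCm39 were used, with no role or order named. The annotation release, the strand setting and the treatment of multimapping reads are not given in the sources used here. Counts of genes with near-identical copies and of overlapping or antisense genes are therefore uncertain. Gene symbols were taken by ID and matched 51948 of the IDs, 16762 of them among the genes tested. Exon overlap was measured in the GENCODE M21 annotation, which is on GRCm38, so no coordinates are given. More than 10% of exonic bases overlapped another gene for Bdnf, Egfl7, H2-Q4, Hopx, Hspa1a, Icam1, Nrarp, Prss23, Selp, Slc26a10 and Sox17. Ntrk2 had no overlap.

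Pairs of libraries within a group differed by a chi-square per degree of freedom of at least 15.3, so none was a duplicate. A count of 0 allows up to 3 counts, and such floors cover counting error only. Computation used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 17072. Counts were scaled by TMM (factors 0.975 to 1.04) and compared by edgeR's robust quasi-likelihood test, hyperoxia against room air, with no covariate. P-values were adjusted by Benjamini and Hochberg, and genes with an adjusted p below 0.05 were called. Adjusted p-values of genes are from this test unless another is named. Levels are in CPM, counts scaled to a common library total after TMM, as mean ± SD with n = 3. Single-library CPM of the Y-linked genes, Xist, Lars2 and the unnamed gene are per total count, without TMM. Standard errors were taken as the log2 fold change over the square root of its F statistic, and 95% limits from them; both are approximate. The common biological coefficient of variation was 0.229.

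Before the data were examined, 35 gene lists were fixed. They cover neurotrophin genes, endothelial identity, subtypes and functions, stress, metabolism, the cell cycle, RNA quality and handling, and markers of other lung cells. Lists were tested with limma's camera on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the lists. Camera called 18 lists, 10 up and 8 down. With the correlation estimated per list, camera called 0; at an unadjusted p below 0.05 stood the p53 targets (0.00896) and the NRF2 targets (0.0378). Fry called 9 lists for a change in 1 direction on balance and 23 for a change in either direction. The 9 were the p53, NRF2, G2 and mitosis, alveolar type 1, endothelial activation, venous, erythroid, TGF-beta and hypoxia lists. Camera did not call the TGF-beta and hypoxia lists.

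Genes were named by a rule fixed at the same time. It took the neurotrophin genes that passed the filter and the 10 largest rises and 10 largest falls among called genes with a symbol that is not a placeholder, a mean of at least 5 CPM and groups that did not overlap. It also took up to 4 called members of each list by size of change, 2 abundant members where none was called, and the most abundant gene. Chosen after their values were seen were Sesn1, Lpl, Pmp22, Hsph1, Ager, Lars2, Xist, the Y-linked genes, and the imprinted and clock genes. Some named members of the lists and 1 test that used such genes are not reported here.

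The test was tried on counts simulated from the real means, with 200 genes changed. It recovered 60% of 100 genes at a log2 change of 1 and 80.8% of 99 at 2, and 11 of its 151 calls (7.28%) were false. Camera found the raised list and called 0 of 20 unchanged lists. Genes were simulated independently of each other, whereas the estimated correlation within the real lists reached 0.93. The trial therefore cannot show how often camera calls real lists falsely. Alternatives fixed beforehand were DESeq2 size factors, upper-quartile scaling and library size only; no filter, or 1 CPM in 3 libraries; each library left out in turn; replicate number as a block; the tests of DESeq2 and limma-voom; thresholds of 0.01 and 0.1; and removal of genes of other cell types. Chosen after seeing the data were Y-linked read status as a term, leaving out hyperoxia 2 with room air 3, and removal of the most abundant unnamed gene. With Y-linked read status as a term, the contrast rests on hyperoxia 2 alone against the room air libraries. Calls gained or lost under that term can therefore reflect hyperoxia 2 itself and do not show dependence on sex.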

Results

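The data describe CD31-selected lung cells of newborn mice kept in room air (21% oxygen) or in hyperoxia (75% oxygen). Such hyperoxia is a model of the lung injury that can follow oxygen treatment of preterm infants. The selection was for endothelial cells, but markers of other lung cells were abundant in the libraries too. Exposure began on postnatal day 0, and the lungs were taken on postnatal day 7, while alveoli are forming. Cells carrying CD31, the adhesion molecule encoded by Pecam1, were pulled out of lung cell suspensions with magnetic beads, and their RNA was sequenced. Each group had 3 libraries. Total counts per library ran from 39379793 to 42343192, and 19471 to 23989 genes were detected. The comparison asked how hyperoxia changed the transcriptome of these cells. From the title of the series, it also asked what became of TRKB, the receptor for brain-derived neurotrophic factor.

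Ntrk2, the gene for TRKB (ENSMUSG00000055254), was 18.3-fold lower in hyperoxia (log2 fold change -4.20, SE 0.37, adjusted p = 0.000312). Its level fell from 170.4 ± 52.4 to 9.28 ± 4.87 CPM (mean ± SD, n = 3 per group). The room air libraries held 172, 222 and 117 CPM and the hyperoxia libraries 14.9, 5.86 and 7.13 CPM. Of the 10 neurotrophin genes tested, 1 fell, 3 rose and 6 did not pass, with the same counts adjusted over the list alone. Sorcs2 and Sort1 encode sortilin family receptors that bind proneurotrophins. Sorcs2 rose from 46.5 ± 8.95 to 117 ± 19.7 CPM (log2 fold change 1.33, SE 0.16, adjusted p = 0.000757). Sort1 rose from 211 ± 24 to 340.3 ± 48.1 CPM (log2 fold change 0.69, SE 0.14, adjusted p = 0.00981). Ntf5, the gene for the TRKB ligand neurotrophin-4, rose from 4.93 ± 0.709 to 9.09 ± 1.2 CPM (log2 fold change 0.88, SE 0.21, adjusted p = 0.0219). That call was lost without room air 1 (adjusted p = 0.0731), room air 2 (0.0858) or hyperoxia 3 (0.108). Bdnf was at 2.63 ± 1.2 CPM in room air and 4.69 ± 1.47 CPM in hyperoxia (log2 fold change 0.83, SE 0.38, adjusted p = 0.208). Ntrk3, the receptor gene for neurotrophin-3, had a log2 fold change of -0.47 (adjusted p = 0.364). Ngfr, Ntf3 and Sorcs1 averaged at most 1.88 CPM in either group and did not pass. Camera did not call the list (adjusted p = 0.0717), but called it up without room air 3 (adjusted p = 0.0381) or hyperoxia 1 (0.0211), with Y-linked read status as a term (0.041) and with replicate number as a block (0.0264).

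**Figure D1:**
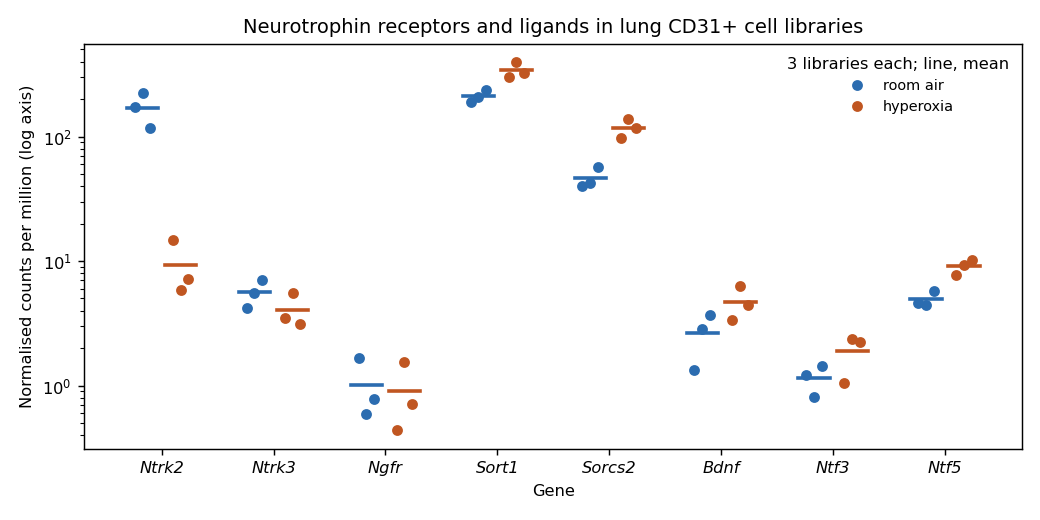
Normalised CPM (log axis) of 8 neurotrophin receptor and ligand genes, with a point for each of the 3 room air and 3 hyperoxia libraries and a line at each group mean. Ntrk2 lies at 117 to 222 CPM in room air and at 5.86 to 14.9 CPM in hyperoxia, while Sort1 and Sorcs2 are higher in hyperoxia.

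Across the transcriptome, 1909 of 17072 tested genes (11.2%) differed between the groups by edgeR, 1156 higher in hyperoxia and 753 lower. Among these, 497 at least doubled and 204 at least halved. The largest rise among the genes chosen by size was that of Eda2r, a receptor of the tumour necrosis factor family, from 1.18 ± 0.0957 to 38.6 ± 9.61 CPM (log2 fold change 5.03, SE 0.23, adjusted p = 2.8e-06). Gdf15, a stress-induced cytokine gene, rose from 4.01 ± 1.65 to 59.7 ± 18.8 CPM (log2 fold change 3.89, SE 0.32, adjusted p = 0.000102). Ddit4l, an inhibitor of mTOR signalling, rose from 1.07 ± 0.327 to 11.4 ± 1.98 CPM (log2 fold change 3.41, SE 0.28, adjusted p = 0.000102). Cdkn1a, the gene for the cell cycle inhibitor p21, rose from 91.9 ± 9.86 to 735 ± 51.9 CPM (log2 fold change 3.0, SE 0.14, adjusted p = 2.8e-06). The next by log2 fold change were the aldo-keto reductase gene Akr1b8 (2.85), interferon-induced Ifit3 (2.81), the activin subunit gene Inhba (2.81), the complement protease gene Masp1 (2.81), the creatine kinase gene Ckmt1 (2.73) and the cytokine gene Lif (2.60). Among the genes chosen by size, Ntrk2 showed the largest fall. Slc26a10, of an anion transporter family, fell from 15.5 ± 4.84 to 1.08 ± 0.404 CPM (log2 fold change -3.83, SE 0.33, adjusted p = 0.000127). Wif1, a secreted Wnt inhibitor, fell from 93.2 ± 13.5 to 23.1 ± 5.64 CPM (log2 fold change -2.01, SE 0.18, adjusted p = 0.000182). Dlk1, a Notch-related membrane protein gene, fell from 91.4 ± 11.5 to 22.8 ± 4.61 CPM (log2 fold change -2.0, SE 0.16, adjusted p = 0.000102). The other large falls were those of the calcium-binding protein gene Cabp1 (-2.16), the transcription factor gene Tcf15 (-2.16), Nell1 (-2.01), Chil3 (-1.94), the cartilage matrix gene Chad (-1.93) and the Rac activator gene Tiam1 (-1.83). Chil3 did not pass without hyperoxia 2 (adjusted p = 0.0529) or with Y-linked read status as a term (0.0895). The groups did not overlap at 5276 genes (30.9%, where chance gives 10%). The 1909 genes became 1057 without room air 2 and 1143 without hyperoxia 3. The higher genes numbered 754, 681 and 713 without room air 1, room air 2 and hyperoxia 3. The lower genes numbered 376, 487, 496 and 430 without room air 2, hyperoxia 1, hyperoxia 2 and hyperoxia 3.

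Genes induced by the tumour suppressor p53 rose together. Of 22 targets tested, 18 rose and 4 did not pass, with a median log2 fold change of 1.37 (camera adjusted p = 2.09e-14; adjusted p = 0.314 with an estimated correlation). Counts adjusted over the list alone were 18 higher and 1 lower, the latter being Sesn1 (log2 fold change -0.32, SE 0.11). Besides Eda2r, Gdf15 and Cdkn1a, the RNA-binding protein gene Zmat3 rose from 22.9 ± 0.363 to 124 ± 18.9 CPM (log2 fold change 2.44, SE 0.13, adjusted p = 7.63e-06). Targets of NRF2, the regulator of the response to oxidative stress, also rose. There 13 of 21 rose and 8 did not pass (median 0.63; camera adjusted p = 9.87e-11; adjusted p = 0.578 with an estimated correlation), and 17 rose when adjusted over the list alone. Gpx2, a glutathione peroxidase gene, rose from 0.866 ± 0.164 to 5.22 ± 1.92 CPM (log2 fold change 2.59, SE 0.36, adjusted p = 0.00165). Nqo1, a quinone reductase gene, rose from 3.73 ± 0.763 to 21.2 ± 1.5 CPM (log2 fold change 2.51, SE 0.19, adjusted p = 9.62e-05). Osgin1 (log2 fold change 2.37, SE 0.19) and the cystine transporter gene Slc7a11 (log2 fold change 2.13, SE 0.30) rose as well. In the same hyperoxia libraries, all 9 markers of alveolar type 1 epithelium rose, with a median log2 fold change of 1.28.

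Genes of cell division fell. All 20 genes of the G2 and mitosis list were lower in hyperoxia, also when adjusted over the list alone. Their log2 fold changes ran from -1.26 to -0.79, with a median of -1.08 (camera adjusted p = 5.83e-13; adjusted p = 0.578 with an estimated correlation). Mki67, the proliferation marker, fell from 112 ± 20.5 to 47.3 ± 5.79 CPM (log2 fold change -1.24, SE 0.15, adjusted p = 0.000816). Tpx2, a spindle assembly gene, fell from 58.5 ± 13.1 to 24.5 ± 5.9 CPM (log2 fold change -1.26, SE 0.20, adjusted p = 0.00272). Cenpf, a kinetochore gene (log2 fold change -1.18, SE 0.17), and Bub1, a checkpoint kinase gene (log2 fold change -1.15, SE 0.21), fell likewise. Of 20 DNA replication genes, 19 did not pass and the list median was -0.27 (camera adjusted p = 0.0775). The replication factor gene Cdc45 fell (log2 fold change -0.84, SE 0.24, adjusted p = 0.0497), but 0 replication genes passed adjusted over the list alone. Cdc45 did not pass without room air 1 (adjusted p = 0.169), room air 3 (0.106), hyperoxia 1 (0.098), hyperoxia 2 (0.103) or hyperoxia 3 (0.119). It did not pass by limma-voom either (adjusted p = 0.0824), scaled by library size only (0.0514) or with Y-linked read status as a term (0.0965). Without room air 2, 4 replication genes fell, and camera called the list down without room air 2 (adjusted p = 1.12e-07) or hyperoxia 3 (0.0397) and with replicate number as a block (0.0445). The alveolar type 1 median in the same comparison was 1.28. The lower replication genes numbered 0 with library size only, the replicate block, limma-voom or hyperoxia 2 and room air 3 left out, 2 with DESeq2 and 3 with no filter on low counts.

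Among endothelial subtypes, 6 of 12 general capillary markers fell, 5 of 12 arterial markers fell and 1 rose, and 4 of 12 venous markers rose. With an estimated correlation camera called none of these 3 lists, and the alveolar type 1 median rose by 1.28 in the same libraries. Of 14 pan-endothelial genes, 1 fell and 13 did not pass, with the same counts adjusted over the list alone (median -0.32; camera adjusted p = 0.0165; adjusted p = 0.688 with an estimated correlation). The gene that fell was Egfl7, which encodes a secreted endothelial protein, from 547 ± 86.6 to 337 ± 32.1 CPM (log2 fold change -0.70, SE 0.14, adjusted p = 0.0112). It did not pass without hyperoxia 3 (adjusted p = 0.0596), and 2 genes of the list fell without room air 3. Camera's call was lost without room air 1 (adjusted p = 0.0958), room air 2 (0.0779) or hyperoxia 2 (0.203). General capillary cells are the capillary type that can divide and renew. Of their 12 markers, 6 fell and 6 did not pass (median -0.62; camera adjusted p = 0.00143; adjusted p = 0.686 with an estimated correlation). The receptor genes Kit (log2 fold change -1.62, SE 0.21) and Glp1r (log2 fold change -1.56, SE 0.21) fell from 466 ± 67.5 to 152 ± 45.9 CPM and from 526 ± 105 to 178 ± 48.1 CPM. The integrin gene Itga1 (log2 fold change -0.92, SE 0.13) and the apelin receptor gene Aplnr (log2 fold change -0.90, SE 0.23) also fell, Aplnr not passing without room air 1 (adjusted p = 0.108), room air 2 (0.111) or hyperoxia 1 (0.0512). Without room air 2, 3 fell. Adjusted over the list alone, 7 fell and 1, the lipase gene Lpl (log2 fold change 0.42, SE 0.13), rose. The lower pan-endothelial genes numbered 2 with library size only, 3 with no filter on low counts, DESeq2 or Y-linked read status as a term and 4 with hyperoxia 2 and room air 3 left out. The higher general capillary genes numbered 1 with no filter on low counts, DESeq2 or Y-linked read status as a term. The lower general capillary genes numbered 3 with the replicate block.

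Aerocytes are the large capillary cells specialised for gas exchange. Of their 14 markers, 4 rose, 1 fell and 9 did not pass, and 5 rose and 1 fell adjusted over the list alone (median 0.22; camera adjusted p = 0.0433; adjusted p = 0.686 with an estimated correlation). Cdkn2b, a cell cycle inhibitor gene, rose from 21.6 ± 1.95 to 79.5 ± 11.9 CPM (log2 fold change 1.88, SE 0.14, adjusted p = 9.62e-05). Emp2, a membrane protein gene that alveolar type 1 cells express too, rose from 933 ± 53.9 to 1510.0 ± 35.4 CPM (log2 fold change 0.70, SE 0.13). Apln, the apelin gene (log2 fold change 0.60, SE 0.13), and Pmp22 (log2 fold change 0.57, SE 0.12) rose, and Fibin fell (log2 fold change -1.29, SE 0.15, adjusted p = 0.000726). Apln did not pass without room air 2 (adjusted p = 0.0639) or hyperoxia 3 (0.0816) or with Y-linked read status as a term (0.0731). The higher aerocyte genes numbered 2 without room air 2. Camera's call was lost without room air 3 (adjusted p = 0.24), hyperoxia 1 (0.19) or hyperoxia 3 (0.0824), with Y-linked read status as a term (0.648) and with a filter of 1 CPM in 3 libraries (0.0622). It was also lost with replicate number as a block (adjusted p = 0.0686) and without hyperoxia 2 and room air 3 together (0.0926).

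Of 12 arterial genes, 5 fell, 1 rose and 6 did not pass (median -0.49; camera adjusted p = 0.00221; adjusted p = 0.686 with an estimated correlation), and 8 fell and 1 rose adjusted over the list alone. Cxcl12, a chemokine gene, fell from 1180.0 ± 289 to 523 ± 57.4 CPM (log2 fold change -1.18, SE 0.19, adjusted p = 0.00306). Sox17, an arterial transcription factor gene, fell from 472 ± 108 to 236 ± 52 CPM (log2 fold change -1.0, SE 0.20, adjusted p = 0.0101). The connexin gene Gja4 fell too (log2 fold change -0.98, SE 0.24), but not without room air 1 (adjusted p = 0.0889), room air 2 (0.0847) or hyperoxia 2 (0.0607). Cdh13, the T-cadherin gene, rose from 39 ± 6.64 to 95.4 ± 8.24 CPM (log2 fold change 1.29, SE 0.14, adjusted p = 0.000402). Without room air 1, room air 2 or hyperoxia 2, 3 arterial genes fell. Of 12 venous genes, 4 rose and 8 did not pass, also adjusted over the list alone (median 0.38; camera adjusted p = 0.00445; adjusted p = 0.578 with an estimated correlation). Selp, the P-selectin gene, rose from 3.52 ± 0.408 to 18.8 ± 2.73 CPM (log2 fold change 2.41, SE 0.19, adjusted p = 9.62e-05). Vcam1, another adhesion gene (log2 fold change 1.0, SE 0.17), Bst1 (log2 fold change 1.11, SE 0.13) and the protease gene Prss23 (log2 fold change 0.99, SE 0.14) rose as well. Selp and Vcam1 were members of the endothelial activation list too, so their rise need not concern venous identity. The venous call was lost without room air 3 (adjusted p = 0.0808) and with Y-linked read status as a term (0.0745). Of 8 lymphatic genes, 2 rose and 6 did not pass, with 4 higher adjusted over the list alone (median 0.41; camera adjusted p = 0.00696; adjusted p = 0.686 with an estimated correlation). The hyaluronan receptor gene Lyve1 rose from 781 ± 79.2 to 1986 ± 175 CPM (log2 fold change 1.35, SE 0.15, adjusted p = 0.000422), and Reln rose (log2 fold change 0.80, SE 0.14). With Y-linked read status as a term the lymphatic call was lost (adjusted p = 0.115). The higher lymphatic genes numbered 4 with no filter on low counts or DESeq2.

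Genes that guide vessel growth went both ways. Of 18 tip cell and sprouting genes, 4 rose, 1 fell and 13 did not pass, and 4 rose and 2 fell adjusted over the list alone (median 0.24; camera adjusted p = 0.0775). Angpt2, the angiopoietin-2 gene, rose from 20.8 ± 2.43 to 35.9 ± 4.14 CPM (log2 fold change 0.79, SE 0.14, adjusted p = 0.00476). The guidance receptor gene Unc5b fell (log2 fold change -0.70, SE 0.19), but not without room air 1 (adjusted p = 0.123), room air 2 (0.161), hyperoxia 1 (0.101) or hyperoxia 2 (0.121). The higher genes numbered 2 without room air 2, 2 without hyperoxia 1 and 1 without hyperoxia 3, and the lower genes 3 without room air 3. Camera called the list up without room air 1 (adjusted p = 0.0368), room air 2 (0.0194) or hyperoxia 2 (0.0439). Of 13 Notch pathway genes, 3 fell and 10 did not pass, with 6 lower adjusted over the list alone (median -0.33; camera adjusted p = 0.0433; adjusted p = 0.686 with an estimated correlation). The pan-endothelial median was nearly the same (-0.32), hyperoxia 2 was the lowest library for both lists, and alveolar type 1 genes rose in the hyperoxia libraries (median 1.28). The ligand gene Jag2 fell from 257 ± 54.2 to 132 ± 16.9 CPM (log2 fold change -0.96, SE 0.16, adjusted p = 0.00402). Nrarp, a feedback inhibitor of Notch, fell (log2 fold change -0.84, SE 0.13), and 79.4% of its exonic bases overlap a gene on the other strand. The receptor gene Notch4 fell (log2 fold change -0.70, SE 0.19), but not without room air 1 (adjusted p = 0.123), room air 2 (0.152), hyperoxia 1 (0.0654), hyperoxia 2 (0.117) or hyperoxia 3 (0.0857). Without room air 3, 7 Notch genes fell. Camera's Notch call was lost without room air 1 (adjusted p = 0.118), room air 2 (0.133), hyperoxia 1 (0.0811) or hyperoxia 2 (0.147), with no filter on low counts (0.0586) and with replicate number as a block (0.0686). The higher sprouting genes numbered 2 with the replicate block. The lower sprouting genes numbered 0 with the replicate block, 2 with library size only, no filter on low counts, DESeq2 or Y-linked read status as a term and 3 with hyperoxia 2 and room air 3 left out. The lower Notch genes numbered 5 with upper-quartile scaling, library size only, a filter of 1 CPM or Y-linked read status as a term, 6 with no filter on low counts or DESeq2 and 7 with hyperoxia 2 and room air 3 left out.

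Of 13 genes of bone morphogenetic protein signalling, 2 rose, 2 fell and 9 did not pass, also adjusted over the list alone (median -0.07; camera adjusted p = 0.772). The ligand gene Bmp4 (log2 fold change 0.60, SE 0.13) and Bmper, which encodes a ligand-binding protein (log2 fold change 1.46, SE 0.40), rose, and the ligand genes Bmp2 (log2 fold change -0.89, SE 0.23) and Bmp6 (log2 fold change -0.74, SE 0.20) fell. The calls of all 4 were lost in some fits with a single library left out, and so with fewer samples. Bmp4 did not pass without room air 2 (adjusted p = 0.0585). Bmper did not pass without room air 1 (adjusted p = 0.108), room air 2 (0.0767), hyperoxia 1 (0.0624) or hyperoxia 2 (0.125), or scaled by library size only (0.0542). Bmp2 did not pass without room air 1 (adjusted p = 0.0727), room air 2 (0.136) or hyperoxia 2 (0.0573). Bmp6 did not pass without room air 1 (adjusted p = 0.109), room air 2 (0.167), hyperoxia 1 (0.0503), hyperoxia 2 (0.122) or hyperoxia 3 (0.1). Of 15 genes of the transforming growth factor beta response, 4 rose and 11 did not pass, also adjusted over the list alone (median 0.03). The adjusted p of this list was 0.112 by camera and 0.0347 by fry. The ligand gene Tgfb2 rose from 66 ± 6.03 to 119 ± 10.8 CPM (log2 fold change 0.85, SE 0.11, adjusted p = 0.00123). Ccn1, a matricellular gene, rose (log2 fold change 1.05, SE 0.23), but not without room air 1 (adjusted p = 0.0555). Itgb6, an epithelial integrin gene, rose (log2 fold change 1.67, SE 0.31), but not with no filter on low counts (adjusted p = 0.13). Of 15 vasoactive genes, 2 rose, 2 fell and 11 did not pass, and 3 rose and 4 fell adjusted over the list alone (median 0.01; camera adjusted p = 0.948). Ptgs2 (log2 fold change 1.71, SE 0.26) and Ptgs1 (log2 fold change 0.92, SE 0.15), the cyclooxygenase genes, rose. Aplnr and the adrenomedullin receptor gene Calcrl (log2 fold change -0.70, SE 0.17) fell. Calcrl did not pass without room air 1 (adjusted p = 0.0738), room air 2 (0.101), hyperoxia 2 (0.0844) or hyperoxia 3 (0.0753). The lower vasoactive genes numbered 0 without room air 1 or room air 2, 1 without hyperoxia 2 or hyperoxia 3, and 4 without room air 3. The higher BMP genes numbered 0 with hyperoxia 2 and room air 3 left out and 1 with library size only. The lower BMP genes numbered 0 with the replicate block. The lower vasoactive genes numbered 0 with the replicate block and 4 with upper-quartile scaling, library size only, no filter on low counts, a filter of 1 CPM, DESeq2, Y-linked read status as a term or hyperoxia 2 and room air 3 left out.

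Of 17 genes of endothelial activation, 5 rose and 12 did not pass, with 6 higher adjusted over the list alone (median 0.42; camera adjusted p = 0.000719; adjusted p = 0.578 with an estimated correlation). Beside Selp and Vcam1, Icam1, an adhesion gene that alveolar type 1 cells express too, rose from 243 ± 25.2 to 678 ± 60.5 CPM (log2 fold change 1.48, SE 0.13, adjusted p = 0.000167). The chemokine gene Cxcl1 rose (log2 fold change 1.57, SE 0.33), as did the E-selectin gene Sele (log2 fold change 1.96, SE 0.40), though Sele did not pass without room air 1 (adjusted p = 0.0519) or hyperoxia 2 (0.0598). Immediate early genes, which cell handling can induce, had a median of 0.53 in the same libraries. Of 21 interferon-stimulated genes, 2 rose and 19 did not pass, also adjusted over the list alone (median 0.06; camera adjusted p = 0.454). Ifit3 rose from 3.19 ± 0.648 to 22.5 ± 3.51 CPM (log2 fold change 2.81, SE 0.21, adjusted p = 9.62e-05), and Ifit2 rose (log2 fold change 0.94, SE 0.17). Of 15 genes of antigen presentation by MHC class I, 2 fell and 13 did not pass, also adjusted over the list alone (median -0.48; camera adjusted p = 0.00473; adjusted p = 0.686 with an estimated correlation). H2-Q4 (log2 fold change -0.70, SE 0.17) and H2-Q6 (log2 fold change -1.75, SE 0.43), whose near-identical copies can share reads, fell. H2-Q4 did not pass without room air 1 (adjusted p = 0.0809), hyperoxia 1 (0.0594) or hyperoxia 2 (0.0697). H2-Q6 did not pass without room air 1 (adjusted p = 0.115) or hyperoxia 1 (0.0618). Without room air 2, 6 genes of the list fell, and camera's call was lost without room air 1 (adjusted p = 0.118) and without hyperoxia 2 and room air 3 together (0.0664). The lower interferon genes numbered 3 with Y-linked read status as a term. The lower MHC class I genes numbered 1 with hyperoxia 2 and room air 3 left out, 4 with the replicate block or DESeq2, 5 with Y-linked read status as a term and 8 with no filter on low counts.

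How many genes of energy and lipid metabolism passed varied by list. Of 25 genes of hypoxia response and glycolysis, 4 rose, 2 fell and 19 did not pass (median 0.20). Adjusted over the list alone, 6 rose and 2 fell. The adjusted p of this list was 0.0841 by camera and 0.0347 by fry. Bhlhe40, a transcription factor gene, rose from 92 ± 11.6 to 157 ± 28.9 CPM (log2 fold change 0.77, SE 0.15, adjusted p = 0.00895). The phosphofructokinase gene Pfkl fell from 128 ± 25 to 78.7 ± 5.28 CPM (log2 fold change -0.70, SE 0.14, adjusted p = 0.0105). The glucose transporter gene Slc2a1 rose (log2 fold change 0.59, SE 0.12), but not without room air 2 (adjusted p = 0.0544). The lipid droplet gene Hilpda fell (log2 fold change -0.67, SE 0.16), but not without room air 2 (adjusted p = 0.0885), hyperoxia 2 (0.0537) or hyperoxia 3 (0.0742). The higher genes numbered 1 without room air 2 and 2 without hyperoxia 2 or hyperoxia 3, and camera called the list up without room air 1 (adjusted p = 0.0492). Of 19 cholesterol synthesis genes, 1 fell and 18 did not pass, with 2 higher and 1 lower adjusted over the list alone (median -0.02; camera adjusted p = 0.522). Stard4, a sterol carrier gene, fell (log2 fold change -0.77, SE 0.15, adjusted p = 0.00783), and 1 gene rose without room air 3 or hyperoxia 1. Of 22 nuclear genes of oxidative phosphorylation, 0 passed by edgeR, 0 by DESeq2, 0 by limma-voom and 0 adjusted over the list alone, and 3 had an unadjusted p below 0.05. Their median was 0.15 (camera adjusted p = 0.00696; adjusted p = 0.686 with an estimated correlation). That call was lost without room air 2 (adjusted p = 0.117) or hyperoxia 1 (0.0552) and with Y-linked read status as a term (0.0745). The ATP synthase genes Atp5b and Atp5a1 had log2 fold changes of 0.26 and 0.10. The higher hypoxia and glycolysis genes numbered 1 with hyperoxia 2 and room air 3 left out and 7 with no filter on low counts. The lower hypoxia and glycolysis genes numbered 1 with the replicate block or hyperoxia 2 and room air 3 left out. The higher cholesterol genes numbered 1 with a filter of 1 CPM, hyperoxia 2 and room air 3 left out or the unnamed gene removed, 2 with no filter on low counts or DESeq2 and 3 with Y-linked read status as a term. The lower cholesterol genes numbered 2 with Y-linked read status as a term.

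Genes of the lists for RNA quality and handling also differed, and whether handling was the cause was not tested. Of 16 dissociation and immediate early genes, 8 rose, 1 fell and 7 did not pass, and 10 rose and 1 fell adjusted over the list alone (median 0.53; camera adjusted p = 0.00119; adjusted p = 0.686 with an estimated correlation). Ier3, an early response gene, rose from 175 ± 51.4 to 342 ± 18.2 CPM (log2 fold change 0.97, SE 0.19, adjusted p = 0.00857). Zfp36, which encodes an mRNA decay factor, rose from 665 ± 125 to 1235 ± 81 CPM (log2 fold change 0.89, SE 0.16, adjusted p = 0.0049). The heat shock protein gene Hsph1 fell (log2 fold change -0.45, SE 0.12). Without room air 1, room air 3, hyperoxia 1, hyperoxia 2 and hyperoxia 3 the higher genes numbered 2, 5, 5, 4 and 3. The lower genes numbered 0 without room air 1, room air 2, room air 3, hyperoxia 1 or hyperoxia 2. Of 13 mRNAs encoded by mitochondrial DNA, 4 rose and 9 did not pass, with 7 higher adjusted over the list alone (median 0.61; camera adjusted p = 0.000814; adjusted p = 0.686 with an estimated correlation). They were mt-Nd3 (log2 fold change 1.51, SE 0.23), mt-Atp6 (log2 fold change 1.20, SE 0.31), mt-Co3 (log2 fold change 1.09, SE 0.30) and mt-Co1 (log2 fold change 0.87, SE 0.25), genes of the respiratory chain whose nuclear copies can share reads. The number was 1 without room air 1, room air 2 or hyperoxia 2 and 7 without room air 3. Of the 4, mt-Nd3 passed without each single library. Calls for mt-Atp6, mt-Co3 and mt-Co1 were lost at adjusted p of 0.0671 to 0.146 without room air 1, room air 2, hyperoxia 1 or hyperoxia 2, 0.0864 to 0.144 without room air 1, room air 2, hyperoxia 2 or hyperoxia 3, and 0.0629 to 0.168 without room air 1, room air 2, hyperoxia 1, hyperoxia 2 or hyperoxia 3. Their calls were also lost for mt-Co3 scaled by upper quartiles (adjusted p = 0.0544), by library size only (0.0615) or by limma-voom (0.0524), for mt-Co1 scaled by upper quartiles (0.0568) or library size only (0.0572), and for mt-Atp6 with Y-linked read status as a term (0.0602). The higher dissociation genes numbered 1 with hyperoxia 2 and room air 3 left out and 4 with Y-linked read status as a term. The lower dissociation genes numbered 0 with the replicate block, Y-linked read status as a term or hyperoxia 2 and room air 3 left out. The higher mitochondrial genes numbered 2 with upper-quartile scaling, library size only or the replicate block, 7 with Y-linked read status as a term, 9 with hyperoxia 2 and room air 3 left out and 10 with no filter on low counts.

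Markers of other lung cells were present in both groups. The highest room air mean of a gene was 10132 CPM in the alveolar type 2 list and 8897 CPM in the fibroblast list. In the pan-endothelial list it was 4584 CPM. Eln, of the fibroblast list, was the top gene of room air 1, room air 2 and hyperoxia 1. Changes in these libraries therefore need not be endothelial. Sftpc, the surfactant protein C gene of alveolar type 2 cells, was the most abundant gene on average. It was at 10132 ± 2678 CPM in room air and 9660.4 ± 1126 CPM in hyperoxia (log2 fold change -0.07, SE 0.22, adjusted p = 0.882). Of 11 alveolar type 2 genes, 0 passed by edgeR, 2 by DESeq2, 0 by limma-voom and 0 adjusted over the list alone, and 3 had an unadjusted p below 0.05. Their median was -0.07 (camera adjusted p = 0.587); 2 rose without room air 3 and 1 fell without room air 1. All 9 alveolar type 1 genes rose, also adjusted over the list alone (median 1.28; camera adjusted p = 6.16e-08; adjusted p = 0.578 with an estimated correlation). Akap5, a kinase anchoring protein gene, rose from 178 ± 43.7 to 622 ± 146 CPM (log2 fold change 1.80, SE 0.21, adjusted p = 0.000586). Spock2, a matrix proteoglycan gene, rose from 302 ± 59.6 to 873 ± 82.2 CPM (log2 fold change 1.53, SE 0.16, adjusted p = 0.000402). The chloride channel gene Clic3 (log2 fold change 1.36, SE 0.18) and the homeodomain gene Hopx (log2 fold change 1.33, SE 0.20) rose too. Mean log2 CPM of the type 1 list lay 1.16, 1.61 and 1.21 above the room air mean in hyperoxia 1, 2 and 3. For the pan-endothelial list the same differences were -0.08, -0.53 and -0.21. The higher type 2 genes numbered 2 with hyperoxia 2 and room air 3 left out. The lower type 2 genes numbered 1 with no filter on low counts and 2 with DESeq2.

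**Figure D2:**
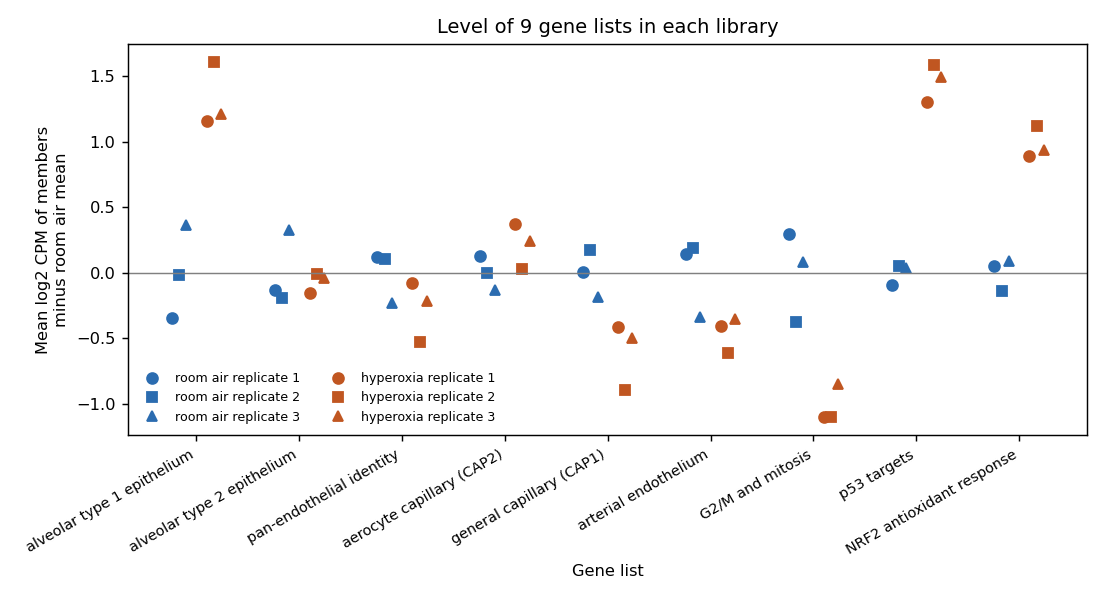
Mean log2 CPM of the members of 9 gene lists in each of the 6 libraries, minus the mean of the 3 room air libraries. Colours mark the groups and marker shapes the replicate numbers, which were not taken to pair the libraries. Alveolar type 1 genes lie 1.16 to 1.61 above the room air mean in hyperoxia, and hyperoxia 2 has the lowest pan-endothelial value (-0.53).

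Other lists of accompanying cells held few changes. Sec14l3, a lipid-binding protein gene of airway epithelium, rose (log2 fold change 1.84, SE 0.19), and 7 of 8 airway genes did not pass (camera adjusted p = 0.112). Camera called the airway list up without room air 3 (adjusted p = 0.0381) and with Y-linked read status as a term (0.00178), and 1 airway gene fell without room air 1 or any single hyperoxia library. Npnt, a matrix protein gene, rose (log2 fold change 1.27, SE 0.16), and 11 of 12 fibroblast genes did not pass (camera adjusted p = 0.926). Rgs5, a G protein regulator of pericytes, rose (log2 fold change 1.11, SE 0.19), and 11 of 12 pericyte and smooth muscle genes did not pass (camera adjusted p = 0.585; 0.0485 with Y-linked read status as a term). Msln, the mesothelin gene (log2 fold change 1.76, SE 0.14), and the keratin gene Krt19 (log2 fold change 1.47, SE 0.18) rose, and 4 of 6 mesothelial genes did not pass (camera adjusted p = 0.587). The mesothelial median was -0.11, of the opposite sign to camera's direction, and 1 gene fell without room air 2. The counts adjusted over the list alone were 2 higher for airway, 1 for fibroblasts and 1 for pericytes, and 2 higher and 2 lower for mesothelium. Of 18 macrophage and monocyte genes, 2 rose, 1, Chil3, fell and 15 did not pass, also adjusted over the list alone (camera adjusted p = 0.252). The scavenger receptor gene Marco rose (log2 fold change 2.22, SE 0.39), but not with no filter on low counts (adjusted p = 0.132). The lysosomal gene Cd68 rose (log2 fold change 0.87, SE 0.22), but not without room air 1 (adjusted p = 0.0738), room air 2 (0.11), hyperoxia 1 (0.0621) or hyperoxia 2 (0.0879). Chil3 did not pass without hyperoxia 2 (adjusted p = 0.0529) or with Y-linked read status as a term (0.0895). Without room air 3, 5 macrophage genes rose, and camera called the list up without room air 3 (adjusted p = 0.00272), without hyperoxia 2 and room air 3 together (0.0102) and with Y-linked read status as a term (0.0485). Itgb3, an integrin gene of platelets, rose (log2 fold change 0.73, SE 0.14), and 9 of 10 platelet genes did not pass, also adjusted over the list alone (camera adjusted p = 0.613). Without hyperoxia 1, 1 platelet gene fell. The higher airway genes numbered 2 with no filter on low counts, DESeq2 or Y-linked read status as a term. The lower airway genes numbered 1 with no filter on low counts or DESeq2. The higher fibroblast genes numbered 2 with Y-linked read status as a term. The lower fibroblast genes numbered 1 with DESeq2 or Y-linked read status as a term. The higher pericyte genes numbered 0 with hyperoxia 2 and room air 3 left out and 3 with Y-linked read status as a term. The lower mesothelial genes numbered 1 with the replicate block or Y-linked read status as a term and 2 with no filter on low counts or DESeq2. The lower macrophage genes numbered 0 with Y-linked read status as a term and 2 with no filter on low counts or DESeq2. The lower platelet genes numbered 1 with no filter on low counts, the replicate block or Y-linked read status as a term.

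Of 6 erythroid genes, 2 fell and 4 did not pass, with 5 lower adjusted over the list alone (median -1.29; camera adjusted p = 0.00107; adjusted p = 0.578 with an estimated correlation). The globin genes Hbb-bt (log2 fold change -2.19, SE 0.53) and Hba-a2 (log2 fold change -1.46, SE 0.37) fell, and reads can be split between them and near-identical copies. Hbb-bt did not pass without room air 1 (adjusted p = 0.0558), room air 2 (0.116) or hyperoxia 3 (0.0848). Hba-a2 did not pass without room air 1 (adjusted p = 0.117), room air 2 (0.0693), hyperoxia 1 (0.0582), hyperoxia 2 (0.056) or hyperoxia 3 (0.0766). The erythroid genes that fell numbered 0 without room air 1, room air 2 or hyperoxia 3 and 1 without hyperoxia 2. Of 12 lymphocyte genes, 0 passed by edgeR, 1 by DESeq2, 0 by limma-voom and 0 adjusted over the list alone, and 2 had an unadjusted p below 0.05. Their median was -0.56 (camera adjusted p = 0.039; adjusted p = 0.686 with an estimated correlation). Cd79a and Cd79b, genes of the B cell receptor, had log2 fold changes of -0.34 and -0.44, and Cd79b passed with no filter on low counts (adjusted p = 0.0372). Camera's lymphocyte call was lost without room air 1 (adjusted p = 0.0958), room air 3 (0.24) or hyperoxia 3 (0.175), and 1 gene fell without room air 1. It was lost with Y-linked read status as a term (adjusted p = 0.415), with a filter of 1 CPM in 3 libraries (0.0777), scaled by library size only (0.0538), by upper quartiles (0.054) and without hyperoxia 2 and room air 3 together (0.136). Of 10 neutrophil genes, 0 passed by edgeR, 0 by DESeq2, 0 by limma-voom and 0 adjusted over the list alone, and 0 had an unadjusted p below 0.05 (camera adjusted p = 0.516). Lcn2, the lipocalin-2 gene, and Ngp, a granule protein gene, had log2 fold changes of 0.39 and -0.22. Lcn2 passed without room air 3 (adjusted p = 0.00625) and with no filter on low counts (0.0323). The lower erythroid genes numbered 4 with no filter on low counts and 5 with DESeq2 or limma-voom. The lower lymphocyte genes numbered 1 with DESeq2 and 3 with no filter on low counts. The higher neutrophil genes numbered 1 with no filter on low counts or hyperoxia 2 and room air 3 left out.

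**Figure D3:**
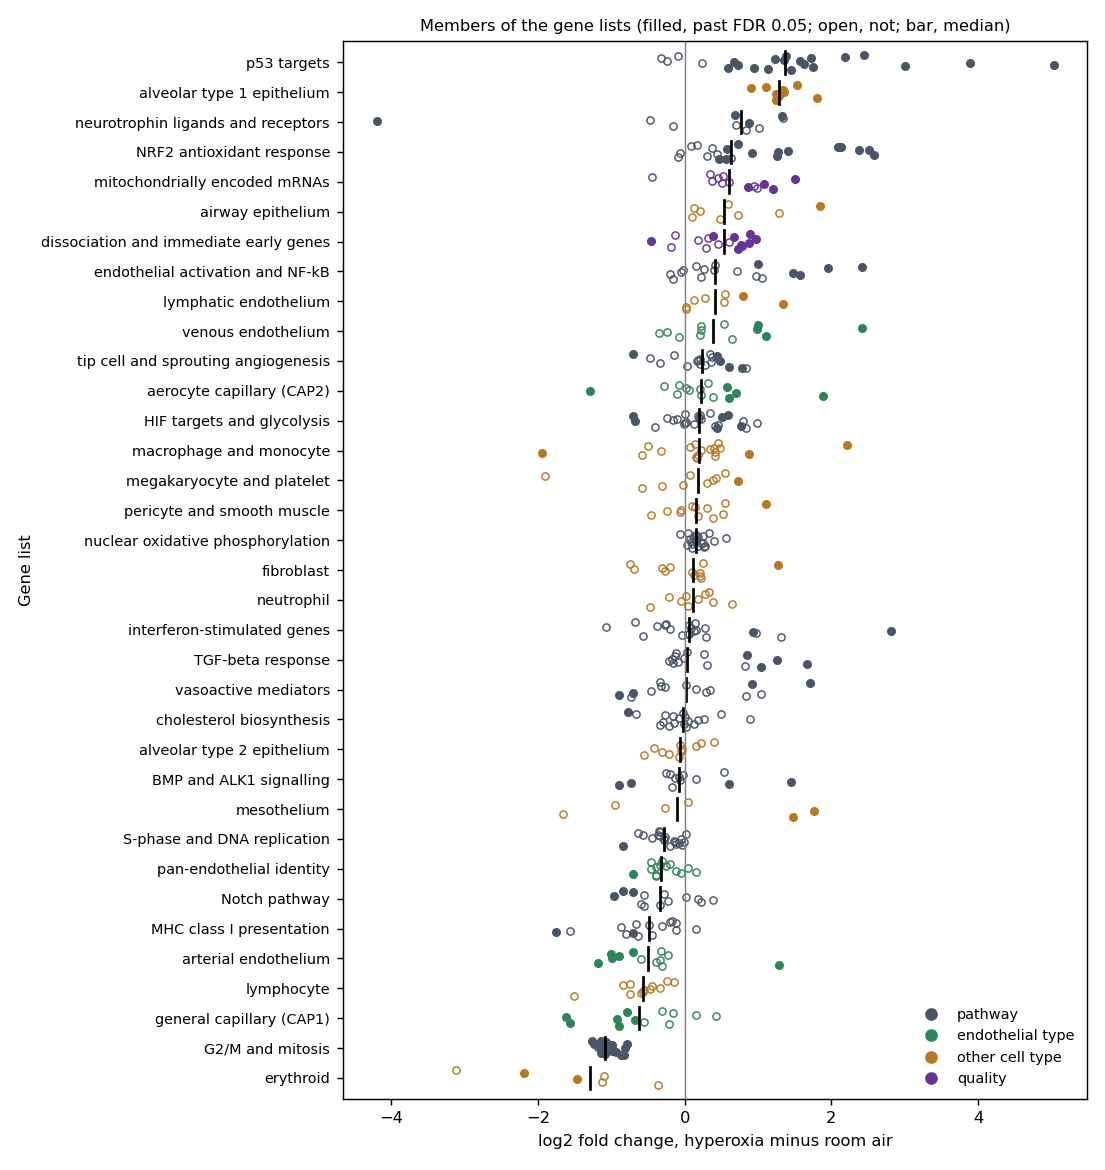
Log2 fold change (hyperoxia minus room air) of each tested member of the 35 gene lists, ordered by their medians; filled points passed an adjusted p of 0.05, open points did not, and bars mark the medians. The medians run from -1.29 for erythroid genes to 1.37 for p53 targets, with alveolar type 1 genes at 1.28 and the 20 genes of G2 and mitosis all below 0.

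The libraries also differed in ways the groups do not name. Summed over the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, room air 1, 2 and 3 and hyperoxia 2 held 129, 162, 158 and 157 CPM. Hyperoxia 1 held 2 counts and hyperoxia 3 held 0 counts, which allows up to 0.0753 CPM. Xist, transcribed from the inactive X chromosome of females, was at 165 CPM in hyperoxia 1 and 235 CPM in hyperoxia 3, and at most 0.904 CPM in the others. Libraries without Y-linked reads were in 1 group only, so the comparison could not be made among them. With Y-linked read status as a term, a model chosen after the data were seen, 2626 genes passed, and 1445 of them were among the 1909, all in the same direction. Then 1223 genes were lower, 1633 at least doubled or halved, and Ntrk2 had a log2 fold change of -4.86. In that model the contrast rests on hyperoxia 2 against the 3 room air libraries. Hyperoxia 2 stood apart on the first principal component, at 89.3 against 10.7 and 14.3 for hyperoxia 1 and 3. Room air lay at -42.6 to -31.5. Hyperoxia 2 also had the fewest detected genes (19471) and the largest mitochondrial share of counts (2.83%, against 1.00 to 1.83% in the others). Its log2 CPM correlated at 0.959 with hyperoxia 1 and 3, which correlated at 0.985 with each other. Hyperoxia 2 held the highest hyperoxia value of 805 of the 1156 higher genes and the lowest of 496 of the 753 lower genes. In room air 3, an unnamed gene took 28257 CPM. Leaving out hyperoxia 2 and room air 3 together gave 1698 genes, 1374 of them shared. That choice ended the calls of Bmper, Bmp4, Ccn1, Cdc45, Bhlhe40, Hilpda, Slc2a1, Sele, H2-Q4, Ier3 and Rgs5, with adjusted p from 0.0514 to 0.166. It also ended camera's calls of the aerocyte, MHC class I and lymphocyte lists and added that of the macrophage list.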

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

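Y-linked read status as a term, leaving out hyperoxia 2 with room air 3, and removal of the unnamed gene were tests chosen only after the results were seen. Against 753 lower genes, no filter on low counts gave 1243 and DESeq2 1206; the cause was not tested. Y-linked read status as a term gave 1223 lower genes and 1633 at least doubled or halved, against 701; the cause was not tested. An adjusted p below 0.01 left 789 of 1909 genes, a stricter choice by construction. Against the 18 lists called of 35, 0 were called with an estimated correlation, where 2 had an unadjusted p below 0.05. Fry called 9 of the 35, among them the TGF-beta and hypoxia lists, which camera had not called. With each library left out in turn, and so fewer samples, 1057 to 1844 genes passed, 681 to 1095 higher and 376 to 749 lower. At least doubled or halved were 534 to 769, called lists numbered 16 to 18, and the log2 fold change of Ntrk2 ran from -4.71 to -3.95. Ntrk2 passed under all settings run, at -4.86 to -3.95. Genes past the threshold numbered 1871 by limma-voom, 1899 with DESeq2 size factors, 1936 with upper quartiles, 1887 with library size only, 2036 with 1 CPM in 3 libraries, 1917 without genes of other cell types, 1698 without hyperoxia 2 and room air 3, and 1917 without the unnamed gene. Of 115 other named genes, 79 kept their direction and side of the threshold under each setting in which they were tested. The thresholds of 0.01 and 0.1 were not applied to single genes, and 92 of the 115 were tested without genes of other cell types and 112 with 1 CPM in 3 libraries. Same-numbered libraries deviated from their group means with correlations of 0.11, -0.04 and -0.09, within the range of the other pairs (-0.12 to 0.15). This gave no sign of pairing by number, but so few libraries cannot exclude it. Replicate number as a block gave 1395 genes, 1350 of them shared, and ended the calls of Aplnr, Unc5b, Notch4, Bmp2, Bmp6, Calcrl, Cdc45, Hilpda, mt-Co3, mt-Co1 and Hba-a2 (adjusted p from 0.0526 to 0.114). It ended camera's calls of the aerocyte (0.0686) and Notch (0.0686) lists and added those of the neurotrophin (0.0264) and DNA replication (0.0445) lists. With no filter on low counts, camera also called the neurotrophin, sprouting, TGF-beta and hypoxia lists (adjusted p from 0.019 to 0.0342).

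The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1909 genes; 1 of the 10, itself, reached this, and likewise the counts of higher, lower, and doubled or halved genes. The highest other split gave 0 by edgeR, with 138 to 878 genes at an unadjusted p below 0.05, against 4298. Each other split has libraries of both groups on both sides, so a real difference widens its spread and lowers its calls. The 0 is therefore no measure of how many calls arise without a difference. For lists called by camera, 3 of 10 splits gave at least 18, and the highest other gave 20. Depth limits genes of low counts such as Ngfr, Ntf3 and Sorcs1, at most 1.88 CPM on average in either group.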

Other observations

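The imprinted and clock gene lists, the tests against alveolar type 2, pan-endothelial and alveolar type 1 genes, and each test with Y-linked read status were chosen only after the results were seen.

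Several imprinted genes active in fetal growth were lower in hyperoxia. Of 13 tested, 4 fell, 1 rose and 8 did not pass (median log2 fold change -0.42; camera adjusted p = 0.033; adjusted p = 0.278 with an estimated correlation), in a list made after 2 members had been seen. Beside Dlk1, Mest, a mesoderm-specific transcript, fell from 576 ± 91.9 to 193 ± 28 CPM (log2 fold change -1.58, SE 0.16, adjusted p = 0.000293). H19, a noncoding RNA, fell from 322 ± 95.4 to 109 ± 3.21 CPM (log2 fold change -1.56, SE 0.19, adjusted p = 0.000726), and Rian, a noncoding RNA of the Dlk1 locus, fell (log2 fold change -1.09, SE 0.27). Igf2r, the receptor that clears insulin-like growth factor 2, rose from 189 ± 22 to 297 ± 20.5 CPM (log2 fold change 0.65, SE 0.12, adjusted p = 0.00726). Igf2 itself had a log2 fold change of -0.66 (adjusted p = 0.173).

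Circadian clock genes differed too, in a list made after 1 member had been seen. Of 15 tested, 5 rose, 1 fell and 9 did not pass (median 0.43; camera adjusted p = 0.00138; adjusted p = 0.278 with an estimated correlation). Nr1d1, the gene for the clock repressor REV-ERB alpha, rose from 17.9 ± 2.2 to 50.6 ± 6.34 CPM (log2 fold change 1.50, SE 0.14, adjusted p = 0.000184). Bhlhe41 (1.34), Tef (0.88), Dbp (0.84) and Cry2 (0.48), also regulators of the clock or its output, rose. Ciart, another clock repressor gene, fell from 18.4 ± 8.86 to 6.93 ± 1.55 CPM (log2 fold change -1.41, SE 0.35, adjusted p = 0.0258). The hour of harvest is not given in the sources used here. In room air 3 the unnamed gene ENSMUSG00000119584 was at 28257 CPM and Lars2 at 751 CPM, against 822 to 2378 and 58.4 to 118 CPM in the other libraries.

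All 9 alveolar type 1 genes rose in hyperoxia, and 0 of them are in another list. A lower endothelial share would raise other cell types alike, but the alveolar type 2 median was -0.0687, against 1.28 for type 1. With Y-linked read status as a term the type 1 median was 1.55. That contrast sets hyperoxia 2, which held Y-linked reads, against the room air libraries, which held them too. The mean log2 CPM of the type 1 list, minus the room air mean, was 1.61 in hyperoxia 2 and -0.35 to 0.36 in room air. The rise was thus seen without a difference in Y-linked reads, but in a single library, so a part of sex in it stays open. More type 1 RNA carried through the CD31 selection, which should remove these cells, predicted that further type 1 genes rise; 11 of 12, picked before their values were seen, rose with a median of 1.48, among them the sodium channel gene Scnn1g (log2 fold change 1.96, SE 0.23) and the basement membrane gene Col4a3 (log2 fold change 1.66, SE 0.20). In room air the type 1 genes lay at 49.5 to 968 CPM, and Ager, the most abundant, rose from 968 ± 212 to 2284 ± 399 CPM; more type 1 RNA may thus stand behind the pattern, and whether hyperoxia left more such cells, changed their recovery or raised these genes within them stays open.

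Ntrk2 fell in all 3 hyperoxia libraries. Fewer endothelial cells would lower general endothelial genes as much, yet the most negative of these was -0.70 (Egfl7), above the upper 95% limit of Ntrk2 (-3.36). With Y-linked read status as a term the log2 fold change was -4.86. That contrast sets hyperoxia 2, which held Y-linked reads, against the room air libraries, which held them too. Ntrk2 was thus lower in hyperoxia 2 without a difference in Y-linked reads. Hyperoxia 2 is a single library, so a part of sex in the whole difference stays open. A fall of Ntrk2 within the selected cells may be one reading, as a hypothesis; loss of a subset of cells that expressed it stays open.

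The p53 targets rose in the libraries in which alveolar type 1 genes rose. For 4 of the 18 (Eda2r, Gdf15, Cdkn1a and Zmat3) the lower 95% limit lay above the highest type 1 gene of either list, Scnn1g (1.96). The limits of Scnn1g itself were 1.45 to 2.47. Those of Zmat3 (2.16 to 2.72) overlap them, and those of Eda2r, Gdf15 and Cdkn1a lie above. These 4 targets rose most and were compared after their values were seen, so the comparison does not decide whether more type 1 RNA was their whole cause. The lower limits of the other 14 did not lie above Scnn1g. For them too a response to oxygen and more type 1 RNA cannot be told apart. With Y-linked read status as a term the median of the 18 was 1.56. That contrast sets hyperoxia 2, which held Y-linked reads, against the room air libraries, which held them too. The mean log2 CPM of the p53 list, minus the room air mean, was 1.59 in hyperoxia 2 and -0.09 to 0.05 in room air. The rise was thus seen without a difference in Y-linked reads, but in a single library, so a part of sex in it stays open. A p53 response to hyperoxia may be one reading, but which cells made the transcripts stays open in bulk RNA.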
